A study of Caenorhabditis elegans with 4 samples.

How the data were processed

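Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was performed, per the labels, on whole L3 larvae of Caenorhabditis elegans strain OP600. The strain carries an integrated unc-62 transgene tagged with TY1, EGFP and FLAG together with an unc-119 rescue gene in an unc-119 mutant. The labels give 4 biological replicates of 1 group and no untagged or mutant group, so the comparisons were between replicates, between peaks and chance, and between gene lists. Replicates 1 and 2 carry a fragment size range of 150 to 350 bp and a stock center as the source (label set A). Replicates 3 and 4 carry microtip sonication and the laboratory itself as the source (label set B).

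The deposited files used here were peak lists on 2 genome builds, ce10 and ce11, with 6 lists per build. The authors deposited 1 list of peaks and background for each replicate, 1 such list for the merged replicates, and 1 list of optimal peaks thresholded by the irreproducible discovery rate (IDR), a measure of whether ranked regions recur between replicates. The notes deposited with the files give the merged list as derived from the alignments of the 4 replicates and a control, and the optimal list as derived from the merged and the replicate lists. The authors' lists give a signal value per region, a −log10 q-value and the offset of the summit. The aligner, the peak caller and their settings are not given in the sources used here, and the alignments, the signal tracks and the control were not analysed here. The deposited lists hold no read counts, so the sequencing depth behind each region is unknown and no interval for depth is given. Signal values of separate lists were on different scales, so they were used to rank regions within a list, and replicates were compared by rank only. Median signal values of the optimal lists on the 2 builds are given as a description. No deposited column of per-sample values was left unused for lack of a sample.

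Coordinates are 1-based on ce11 (WBcel235). All ce11 regions lay within the chromosome lengths of the reference. Genes were taken from Ensembl release 115, with 19973 protein-coding genes on the 6 nuclear chromosomes. No coordinate was converted between builds, and the ce10 lists entered only counts, overlaps and medians.

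K denotes the number of optimal peaks, 1037. An optimal peak was supported by a replicate when at least 1 bp was covered by 1 of the K highest-signal regions of that replicate. Pairs of replicates were compared by the mean share of each one's K highest regions that overlapped those of the other. Each summit received 1 class by priority: promoter (within 1000 bp upstream of a protein-coding transcript start), 5' UTR, coding exon, 3' UTR, intron or intergenic. Class shares were tested against 1000 circular shifts of the summits within each chromosome, two-sided, for which the smallest p is 0.002. Support, with summits within 100 bp, was set beside the same shifts without a p-value, because the optimal list was derived from these same replicates. A gene was called bound when an optimal summit lay from 1000 bp upstream to 200 bp downstream of the start of any of its transcripts. The 22 gene lists were compared with all other protein-coding genes by Fisher's exact test. The lists were Hox cluster and TALE homeodomain genes, vitellogenins, intestine, cuticle collagens, hypodermis and seam regulators, heterochronic pathway, vulval induction and Ras pathway, Notch pathway, Wnt pathway, pan-neuronal genes, neuron identity regulators, body wall muscle, pharynx, germline, insulin signalling and longevity, ribosomal proteins, histones, homeobox genes with ceh symbols, nuclear hormone receptors, bHLH factors, seven-transmembrane chemoreceptors and F-box A genes. The 9 motifs were searched on both strands within 50 bp of the summit and in a window of equal size centred 250 bp to 1 side, drawn at random for each peak, and compared by an exact McNemar test. Peaks per chromosome were tested by an exact binomial test. Rank correlations across peaks were tested with 100000 resamples. The Benjamini-Hochberg adjustment was made within each family (6 chromosomes, 6 classes, 22 lists, 9 motifs), with a threshold of 0.05. The 2 rank correlations with signal had no adjustment fixed in advance; an adjustment over both was decided after their p-values were seen, and both p-values are given. Confidence intervals are at 95%, and odds ratio intervals are exact. Peaks and genes are not replicates: p-values over them do not measure the spread between cultures. Values per replicate were therefore computed from each replicate's own K highest-signal regions, without mitochondrial regions, and are given as mean ± SD; support and the pairs of replicates include mitochondrial regions.

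Lists, motifs, tests and the rule for named genes were fixed before the data were examined. The rule took the gene with the nearest start, within 5000 bp, for each of the 20 strongest optimal peaks, up to 4 bound members of each list by signal value, and 14 genes whatever their values: unc-62, ceh-20, ceh-40, ceh-60, ceh-13, lin-39, mab-5, egl-5, php-3, nob-1, unc-119, elt-2, vit-2 and vit-6. Alternatives covered the build, K, the overlap criterion, the promoter window, the gene assignment, the background, the motif window and control, the strength and support of peaks, and each replicate left out in turn. Leaving out a replicate kept only the optimal peaks supported by the other 3. The optimal list itself, made from all 4 replicates, was not made anew. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used.

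The functions were tested on simulated data. With bound genes drawn at random among 19973, the list test made 5 calls in 2200 tests, and a list bound 10 times as often was called in 100 of 100 runs. In the data a summit can bind divergent genes together, as at his-67 and his-68, and the random draws do not cover that. For 1037 simulated summits, the location test called 0 of 20 runs without an effect and 20 of 20 with 40% of summits moved into promoters. With TGACAG written into 8% of 1037 windows the motif test called 100 of 100 runs, against 4 of 100 without it. These windows lay away from the summits and were not chosen to differ in GC content from their flanks. The real summit windows do differ, so the rate without the site does not cover that difference. The rank correlation test called 6 of 100 runs with no relation, and 526 of 526 copied peaks were found by the overlap.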

Results

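The binding of UNC-62 was mapped in L3 larvae. UNC-62 is a homeodomain protein of the TALE class, a nematode member of the Homothorax and MEIS family, whose relatives bind DNA together with PBX-type and Hox proteins. The labels describe ChIP-seq against eGFP-tagged UNC-62 in whole larvae of mixed sex, with 4 biological replicates. The lists of peaks and background held 30000 regions for each of replicates 1, 2 and 3, and 28073 for replicate 4. The merged list held 18556 regions and the optimal list 1037 peaks, which were the 1037 regions of highest signal in the merged list. Optimal peaks had a median width of 356 bp and a median signal value of 50.5, with a range of 37.3 to 243.8, where signal is the authors' value per peak.

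The 20 strongest peaks included peaks at the ribosomal protein genes rpl-3, rpl-35 and rpl-15, at unc-62 itself and at ceh-20, which encodes a PBX-type partner of UNC-62. The peak of highest signal (243.8; III, 3867454 to 3867692) had its summit in the promoter of rpl-3 (WBGene00004414), 282 bp upstream of a start. The second (222.7; III, 10759131 to 10759370) lay 57 bp upstream of tasp-1 (WBGene00010480), which encodes a taspase-type protease. The third (217.2; III, 6979020 to 6979314) lay in the ceh-20 promoter (WBGene00000443; gene at III, 6979884 to 6981785), 719 bp upstream of its start. It ranked 3, 10, 35 and 37 in the lists of replicates 1 to 4.

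Among the other 20 strongest peaks, promoter summits lay 158 bp upstream of cdc-48.1 (signal 216.7; II, 10563474 to 10563679), which encodes the p97-type AAA ATPase. Further promoter summits lay 707 bp upstream of nspc-17 (216.7; X, 14525774 to 14526001), 682 bp upstream of zfp-1 (171.7; III, 8802073 to 8802239), 450 bp upstream of rpl-35 (167.4; III, 7854595 to 7854779) and 347 bp upstream of rpl-15 (156.6; IV, 654849 to 655025). A peak at sma-9 (204.7; X, 10766127 to 10766346), the Schnurri-type factor of the body size pathway, was intergenic, 3052 bp upstream of the start. The peak nearest to casc-3 (197.0; I, 13337204 to 13337398) was intergenic, 1145 bp upstream. The peak in pqn-41 (173.4; III, 1925289 to 1925528) was intronic. Of these 20 peaks, 17 were among the 1037 highest regions of all 4 replicates and 3 were among those of 3 replicates.

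By chromosome, X held more optimal peaks than its length would give and chromosomes IV and V fewer. X carried 249 of 1037 peaks, 24% (95% exact interval 21.4 to 26.7%) against 17.7% of the assembled length, a fold of 1.36 (exact binomial test, adjusted p = 1.61e-06). Chromosome IV carried 133 peaks, a fold of 0.735 (exact test, adjusted p = 1.18e-04), and V carried 162, a fold of 0.749 (adjusted p = 6.42e-05). The share on X in the replicates' own highest regions was 23% ± 0.933 (SD, n = 4). Chromosomes I, II and III did not pass the test, with folds of 1.07, 1.03 and 1.14. Against the rest of the merged list, X held 1.22 times the odds and IV 0.77 times (Fisher's exact test, adjusted p = 0.0246 for each), while V, with 0.828 times the odds, did not pass (adjusted p = 0.062).

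The first comparison asked how far the optimal peaks recurred in single replicates. The 1037 highest regions of replicate 1 overlapped 78.9% of the optimal peaks, those of replicate 2 overlapped 59.8%, those of replicate 3 overlapped 51.5% and those of replicate 4 overlapped 32.2% (mean 55.6% ± 19.4, SD, n = 4). With summits within 100 bp the shares ran from 76.2% in replicate 1 to 24.8% in replicate 4, against means of 0.208 to 0.216% in the shifts. Support above chance, and its rise with signal, follow from how the list was made. Its peaks are the 1037 regions of highest signal in the merged list, and that signal comes from the merged reads of these replicates. The 146 peaks supported by all 4 replicates had a median signal of 89.5, the 274 supported by 3 had 61.2, the 318 supported by 2 had 48.6, the 264 supported by 1 had 41.7, and the 35 supported by none had 38.5. The number supported by all 4 was 83 with 518 regions per replicate and 247 with 2074, 92 with summits within 100 bp, and 309 without replicate 4.

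**Figure D1:**
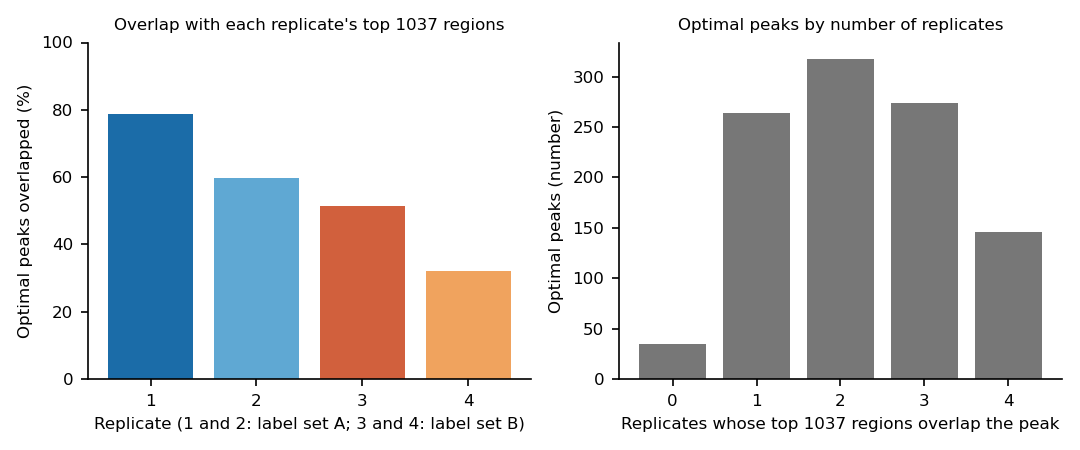
The left panel plots the percent of the 1037 optimal peaks overlapped by the 1037 highest-signal regions of each replicate, 1 bar per replicate. The right panel plots the number of optimal peaks by the number of replicates that overlap them; 146 were overlapped in all 4 and 35 in none.

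The second comparison set pairs of replicates with the same label set beside pairs across label sets. Replicates 1 and 2 shared 51.1% of their highest regions and replicates 3 and 4 shared 28%. Across label sets the shares were 43.5% for replicates 1 and 3, 37.4% for 2 and 3, 27.8% for 1 and 4 and 23.3% for 2 and 4. The mean within label sets was 39.6% and across them 33%, a difference of 6.55 percentage points. The highest regions of replicates 3 and 4 included 29 and 30 mitochondrial regions, absent from replicates 1 and 2. With nuclear regions only, chosen after seeing the data, replicates 3 and 4 shared 26.1% and the difference was 5.20 points. With 3 ways to pair 4 replicates, the exact permutation p was 0.333 (one-sided), the smallest the design allows. Across the optimal peaks listed in both replicates, Spearman's rho of signal was 0.357 for replicates 1 and 2, 0.309 for 3 and 4, and 0.207 to 0.315 across label sets; peaks are not independent replicates.

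The third comparison asked where in the annotation the summits lay. Summits were in promoters and intergenic sequence more often than shifted summits, and in coding exons far less often. Promoters held 429 summits, 41.4%, against a mean of 21.9% in the shifts (central 95% of shifts 19.3 to 24.5%; fold 1.89; adjusted p = 0.0024 by permutation). Intergenic sequence held 34.7% against 25.1%. Coding exons held 14 summits, 1.35%, against 21%, a fold of 0.0643. Introns held 20% against 28.5% and 3' UTRs 0.771% against 2.44%, all with adjusted p = 0.0024 by permutation. The 5' UTR share, 1.83% against 1.10%, did not pass (permutation test, adjusted p = 0.0579). The median distance from a summit to the nearest start was 1099 bp against a mean of 1344 bp in the shifts (p = 0.002 by permutation, the smallest they can give), and 88 summits lay over 5000 bp from any start.

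Single replicates showed the promoter and coding exon contrasts as well. The promoter share of each replicate's own highest regions was 40.3%, 40.4%, 39.5% and 30.7% in replicates 1 to 4 (mean 37.7% ± 4.71, SD, n = 4), each above its shifts by permutation with an adjusted p of 0.0024 to 0.006. The coding exon share was 1.35%, 3.28%, 3.87% and 12%, so replicate 4 stood apart from the other replicates. The low 3' UTR share was seen only in replicates 1 and 2 (0.771% in each), with 2.58% in replicate 3 and 3.38% in replicate 4. Against the remaining 17519 regions of the merged list, optimal summits were also more often in promoters (28.8% of the remaining regions; odds ratio 1.74, Fisher's exact test, adjusted p = 2.09e-16).

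**Figure D2:**
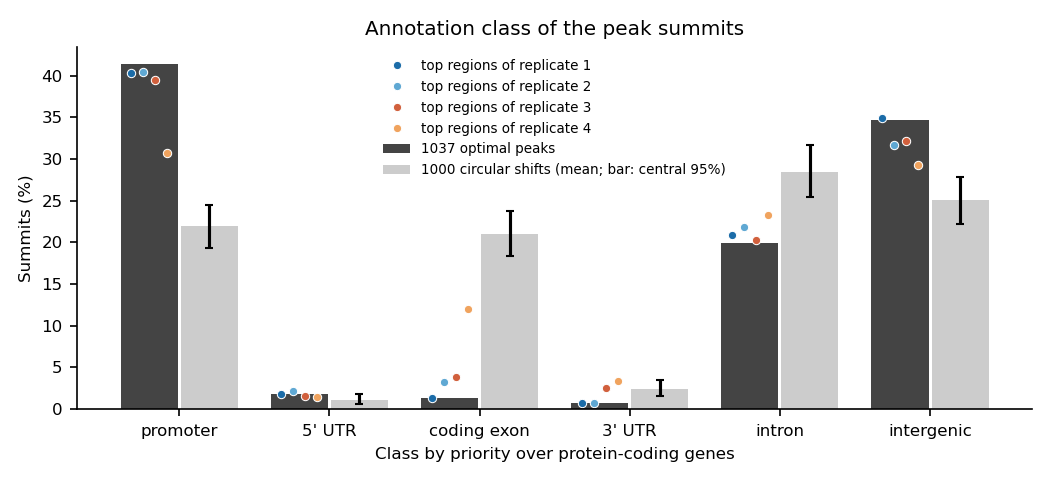
The percent of summits in each annotation class is plotted for the 1037 optimal peaks (dark bars), for 1000 circular shifts (grey bars, mean with the central 95%) and for the highest-signal regions of each replicate (points). Promoters held 41.4% of optimal summits against 21.9% in the shifts, and coding exons 1.35% against 21%.

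The fourth comparison asked which gene groups had a summit at a start. UNC-62 summits lay at 525 of 19973 protein-coding genes, 2.63%, against a mean of 280.9 genes in the shifts. Of 22 lists, 4 were bound more often than other genes (Hox cluster and TALE homeodomain genes, ribosomal proteins, the heterochronic pathway and pan-neuronal genes), and seven-transmembrane chemoreceptors were bound less often.

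Of the 12 Hox cluster and TALE homeodomain genes, 5 were bound, 41.7% against 2.61% of other genes (odds ratio 26.7, 95% interval 6.66 to 98; Fisher's exact test, adjusted p = 6.14e-05). The 5 were unc-62 (signal 210.5) and ceh-20 (217.2) of the TALE class, and lin-39 (70.4; III, 7534655 to 7535010), ceh-13 (54.4; III, 7554890 to 7555245) and mab-5 (42.1) of the Hox genes, which pattern the body axis. Among these Hox peaks, that of ceh-13 was among the highest regions of 3 replicates, that of lin-39 of 2 and that of mab-5 of 1. In the replicates' own highest regions the bound share was 31.3% ± 7.98 (SD, n = 4). The posterior Hox gene egl-5 had 3 regions of the merged list within 5000 bp but no optimal peak, and its nearest optimal peak was 30005 bp from a start. For php-3 and nob-1 the nearest optimal peaks were 74126 and 76005 bp away. The PBX-type genes ceh-40 and ceh-60 were not bound, with nearest optimal peaks 42446 and 14682 bp away. Regions of the merged list within 5000 bp numbered 3 at ceh-60, 1 at nob-1 and 0 at php-3 and ceh-40. With a window of 500 bp upstream the Hox and TALE list did not pass, with a fold of 8.64 beside 16 (exact test, adjusted p = 0.12).

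Of 81 ribosomal protein genes, 24 were bound, 29.6% against 2.52% of other genes (odds ratio 16.3, 95% interval 9.58 to 26.9; Fisher's exact test, adjusted p = 8.88e-18). The strongest were rpl-3, rpl-35, rpl-15 and rpl-20 (signal 130.9; IV, 4750007 to 4750163). In the replicates' own highest regions the bound share was 29.6%, 23.5%, 18.5% and 11.1% in replicates 1 to 4 (20.7% ± 7.83, SD, n = 4), and the list was called in each of the 4. The share of these genes with a region of the merged list in the window was 84.0%.

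Of the 14 protein-coding members of the heterochronic pathway, which times larval cell fates, 3 were bound (odds ratio 10.2, 95% interval 1.81 to 38.6; Fisher's exact test, adjusted p = 0.0258). They were nhl-2 (signal 147.6; III, 4899841 to 4900017), lin-28 (58.0; I, 8409833 to 8410188) and lin-66 (56.6; IV, 13887545 to 13887900). Of the 5 microRNAs of the pathway, counted but not tested, lin-4 and mir-241 had an optimal summit within 1000 bp, 458 and 461 bp away. Of 28 pan-neuronal genes, 4 were bound (odds ratio 6.21, 95% interval 1.56 to 18.2; adjusted p = 0.0258 by the same exact test). These were unc-108, a Rab2 GTPase (74.9), syd-2, a liprin (69.6), unc-18, a Munc18-type protein (57.2), and rgef-1, a neuronal guanine nucleotide exchange factor (40.1). The heterochronic list was called in 3 single replicates and the pan-neuronal list in 1. With a replicate left out, only peaks supported by the other 3 were kept, and each such set holds the peaks supported by all 4. The pan-neuronal call was lost whichever replicate was left out, with folds of 7.91 to 10.03 beside 5.47 in the full set. The heterochronic call was lost without replicate 1, 2 or 3, with folds of 15.8 to 20.1 beside 8.19. Both were lost with support in all 4 replicates (folds of 23.4 and 11.7) and with 500 bp upstream (7.41 and 5.57), and the heterochronic call also with GC strata (odds ratio 7.42, exact test, adjusted p = 0.0519). The rgef-1 peak was among the highest regions of no replicate. Among only the genes with a region of the merged list in the window, neither list passed (folds of 3.70 and 2.34, exact test, adjusted p = 0.225 and 0.38). On that background the lists that stayed called had smaller contrasts too: 4.04 beside 11.8 for ribosomal proteins, 6.96 beside 16 for Hox and TALE genes, and 0.208 beside 0.0791 for chemoreceptors.

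Of 1353 seven-transmembrane chemoreceptor genes, 3 were bound, 0.222% against 2.80% of other genes (odds ratio 0.077, 95% interval 0.0158 to 0.227; Fisher's exact test, adjusted p = 1.68e-11). The 3 were str-176, srh-2 and srh-76. The share was below that of other genes in all 4 replicates. Among the fewer peaks supported in all 4 replicates the call was lost (exact test, adjusted p = 0.156). It was likewise lost in the overlapping sets without replicate 1, 2 or 3 (exact test, adjusted p = 0.111, 0.115 and 0.221). The folds in these sets were 0 to 0.162.

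The remaining 17 lists did not pass in the main setting. In the Wnt pathway 2 of 27 genes were bound, mig-5, a Dishevelled (signal 80.9), and pry-1, an Axin (53.5). The insulin and longevity list had 2 of 31, mdl-1 (69.8) and akt-2 (52.2). Nuclear hormone receptors had 10 of 269, led by nhr-49 (69.5), nhr-35, nhr-1 and nhr-48. Histones had 3 of 50 (his-37 with 149.0, his-67 and his-68), and homeobox genes with ceh symbols 3 of 63, namely ceh-20, ceh-38 and ceh-13. Cuticle collagens had 3 of 175 (col-38, col-93 and col-103). A single member was bound among intestinal genes (acs-2, of 25), body wall muscle genes (unc-112, of 34), germline genes (cgh-1, of 38), bHLH factors (hlh-11, of 25) and F-box A genes (fbxa-90, of 169). None was bound among 6 vitellogenins, 28 hypodermis and seam regulators, 26 vulval and Ras genes, 17 Notch genes, 37 neuron identity regulators and 18 pharyngeal genes, whose exact 95% upper limits on the odds ratio ran from 3.89 for neuron identity regulators to 31.5 for vitellogenins. The nearest optimal peaks to starts of elt-2, the main intestinal GATA factor, and of the yolk protein genes vit-2 and vit-6 were 45468, 15460 and 46084 bp away. Below the optimal set, elt-2 had 6 regions of the merged list within 5000 bp (best rank 2108), vit-2 had 1 (rank 5380) and vit-6 had 0.

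**Figure D3:**
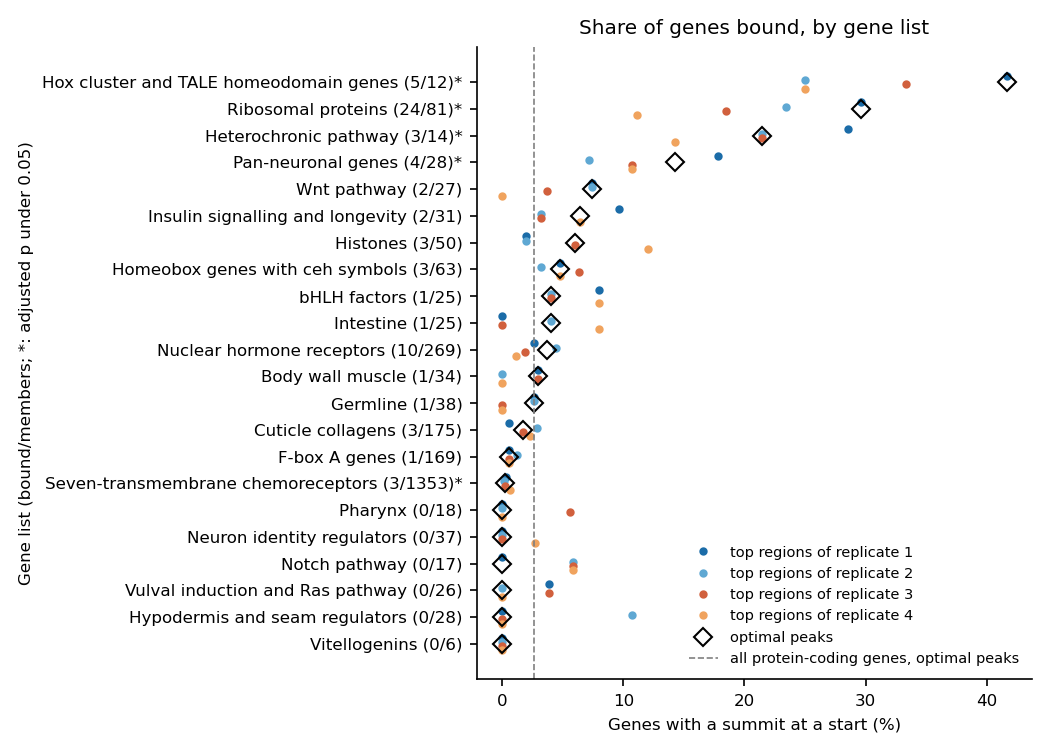
The percent of genes with a summit from 1000 bp upstream to 200 bp downstream of a start is plotted for each list, for the optimal peaks (diamonds) and for the highest-signal regions of each replicate (points). The dashed line marks 2.63% of all protein-coding genes; Hox and TALE genes reached 41.7% and ribosomal proteins 29.6%.

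The fifth comparison asked which motifs lay at the summits. The TGACAG core bound by MEIS and Homothorax proteins and the TGATTGAT site of PBX with Hox proteins were both more frequent at summits than beside them. TGACAG lay within 50 bp of 105 summits, 10.1%, against 2.12% of flanking windows (exact McNemar test, adjusted p = 1.89e-13). Other controls held it more often: 3.33% of windows on both flanks, 3.86% of promoter-matched windows and 5.11% of summits in the rest of the merged list. The contrasts were then smaller, with folds of 3.04 and 2.63 and an odds ratio of 2.09, beside a fold of 4.77. TGATTGAT lay at 3.57% against 0.386% (exact test, adjusted p = 3.08e-07), its degenerate form TGATNNAT at 13.1% against 8% (adjusted p = 2.13e-04), and the composite TGATTGACAG at 6 summits against 0 flanks (adjusted p = 0.0402). The composite, on these few sites, did not pass with 25 bp on each side (exact test, adjusted p = 0.321), among the 518 peaks of higher signal (0.161) or with any replicate left out (0.294 to 1). TGATTGAT did not pass without replicate 1, 2 or 3 (exact test, adjusted p = 0.884, 0.884 and 0.608), with folds of 2, 2 and 3. Each set with a replicate left out holds the 146 peaks supported by all 4, so these are not separate tests. TGATTGAT passed without replicate 4 (exact test, adjusted p = 0.0125, fold 7). TGATNNAT did not pass with 25 bp on each side (6.27% against 4.34%, exact test, adjusted p = 0.0967) or without replicate 1, 2 or 3 (folds of 1.67, 1.73 and 1.40). In the replicates' own highest regions TGACAG lay at 8.22% ± 2.02 and TGATTGAT at 2.46% ± 1.04 of summits (SD, n = 4). Of the 179 other orders of the letters of TGACAG, 1 reached as high a share: GTGACA, with 11.8%. It overlaps TGACAG by 5 bases, and 32 of the 105 windows with TGACAG held GTGACAG, which contains both. By fold over flanks, 1 other order, CGTCTA, was at or above TGACAG (4.88 against 4.77).

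Other motifs moved as well. GAGAGAGA lay at 9.55% of summits against 2.70% of flanks (adjusted p = 1.00e-10) and the E-box CACGTG at 4.34% against 1.16% (adjusted p = 1.25e-05), while the homeodomain core TAATTA was less frequent at summits, 1.25% against 4.05% (adjusted p = 1.47e-04), all by the exact McNemar test. The GATA site WGATAR (20% against 23.1%) and TGACTCA (0.482% against 0.675%) did not pass. Summit windows held 47.4% ± 7.23 GC and flanks 36.8% ± 9.08 (SD over 1037 peaks). Against shuffled bases of the same summit windows, a control chosen after seeing the data, TGACAG was 2.42 times and TGATTGAT 11.8 times as frequent. Beside promoter-matched windows the E-box did not pass (exact test, adjusted p = 0.21), and among the 146 peaks supported by all 4 replicates TGACAG alone passed (15.1% against 4.11%, adjusted p = 0.0335). In that smaller set other folds were CACGTG 4 (3.75 in the full set), TGATNNAT 1.64 (1.64), TAATTA 0.2 (0.31), TGATTGAT 2 (9.25) and GAGAGAGA 1.64 (3.54).

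**Figure D4:**
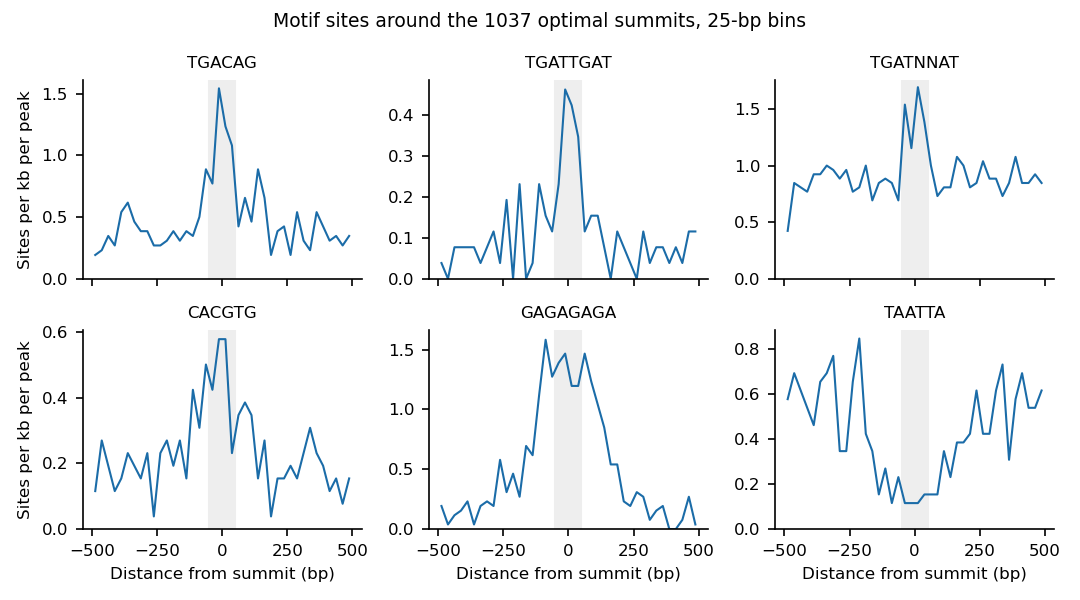
Each panel plots the number of sites of 1 motif per kb and peak in bins of 25 bp from 500 bp upstream to 500 bp downstream on the chromosome, averaged over the 1037 optimal summits; the grey band marks the 50 bp on each side used in the tests. TGACAG, found at 10.1% of summits, rises at the summit, and TAATTA, found at 1.25%, falls there.

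With sites within 50 bp and promoters of 1000 bp, neither the TGACAG site nor promoter location passed the test against peak strength after adjustment. The site was present at 13.5% of the 260 strongest peaks and at 10% of the 259 weakest, with 10.8% and 6.18% in the groups between (Spearman's rho 0.0562, permutation test, p = 0.0703, adjusted p = 0.0703). Promoter summits made up 41.5% of the strongest and 35.5% of the weakest, with 47.5% and 40.9% between (rho 0.0626, permutation test, p = 0.0434, adjusted p = 0.0703). With sites within 25 bp the TGACAG relation passed (rho 0.0714, permutation test, adjusted p = 0.0423). The adjustment over these 2 relations was decided after the p-values were seen. Both relations are across peaks of 1 list, which are not replicates.

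The loci carried by the transgene were described next. At unc-62 (WBGene00006796; V, 4497461 to 4511449) with 5000 bp on each side, the merged list held 26 regions, 5.86 times the number expected from the length, and 10 of the optimal summits lay there. The best rank at this locus was 2, 1, 21 and 22 in the lists of replicates 1 to 4, which held 26, 29, 29 and 24 regions. Among nuclear regions only, these ranks were 2, 1, 3 and 3. The strongest peak (signal 210.5; V, 4499362 to 4499787) lay 68 bp inside a transcript start, and beyond the stretch another (163.3; V, 4491392 to 4491569) lay 5985 bp upstream in intergenic sequence. At unc-119 (WBGene00006843; III, 10902641 to 10908935) the merged list held 1 region, of rank 745, and the best ranks in replicates 1 to 4 were 403, 2300, 17150 and 27561.

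**Figure D5:**
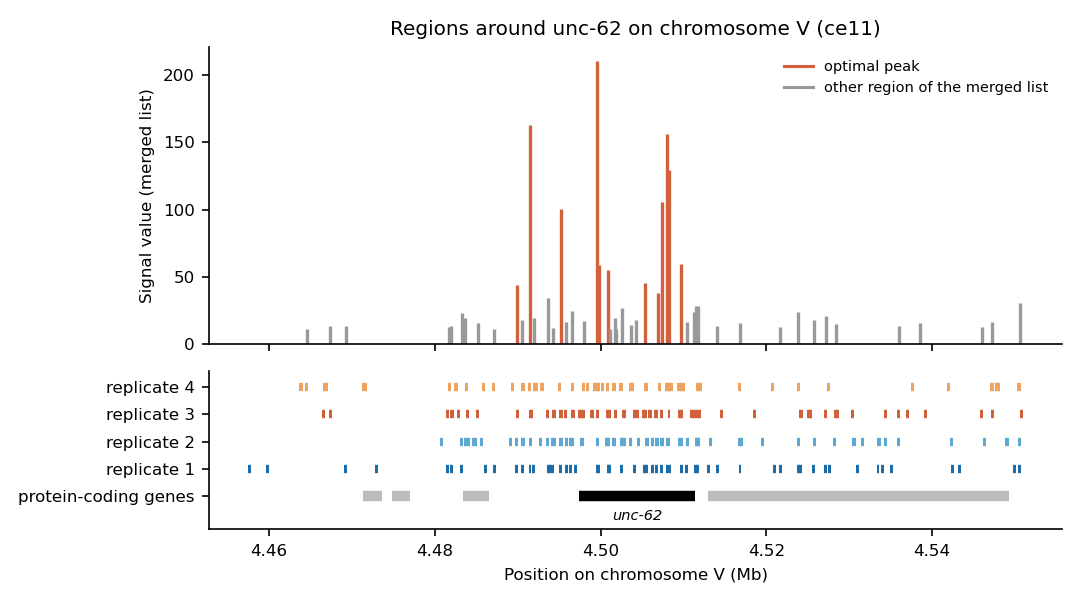
The map shows chromosome V around unc-62 on ce11, with position in Mb on the horizontal axis. Above, lines give the signal value of each merged-list region at its summit, with optimal peaks in orange; below, bars give regions of the 4 replicates and protein-coding genes. The highest line, 210.5, lies within unc-62.

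On ce10 the optimal list held 994 peaks against 1037 on ce11, with a median signal of 50.8 against 50.5. The merged lists held 18790 and 18556 regions. On ce10, 144 peaks were supported by all 4 replicates.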

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

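The tests of extra transgene copies and both tests of replicate 4 were chosen after the result was seen; the predictions for the tests at ribosomal protein promoters were written before those tests were run, but after the enrichment was seen. The labels give 1 group, so for the unc-62 locus and replicate 4 no biological explanation was tested.

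Regions were dense at unc-62, where the gene body held 18 regions of the merged list against 9 at the 99th percentile of stretches of that length on chromosome V. At unc-119, with 5000 bp on each side, there was 1 region against 7 at the 95th percentile on chromosome III. Copies of the rescue gene would add no regions at unc-62, so this cannot judge them as a cause there. The rescue gene comes together with the transgene, and its locus showed no excess of regions. Which part of unc-119 it holds was not examined, so this does not settle the number of copies. Extra copies of the unc-62 transgene stay open: the flanks to 10000 bp beyond the gene held 13 regions, just above the 99th percentile of 12. The excess was on 1 side, with 9 regions in the left flank and 4 in the right, and the left flank also carries 3 optimal peaks. Binding of UNC-62 to its own gene may contribute and was not tested here.

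Ribosomal protein genes were bound at 24 of 81 starts. High promoter GC content is argued against as the whole cause, because the median promoter GC content was 35.5% for these genes and 34.3% for all genes. The odds ratio stratified over 5 classes of GC content was 14.1 (exact test, p = 2.86e-18) beside 16.3 without strata. With so small a difference in GC content, the strata could hardly move it. The strata cover whole promoters, and GC content at the summits themselves was not adjusted for. Nearly all summits at ribosomal protein starts lacked the MEIS core site within 50 bp: TGACAG lay at 1 of 24, 4.17%. Whether it is rarer there than at other promoter summits cannot be told, because the 24 summits are too few. It lay at 33 of 405 other promoter summits, 8.15% (Fisher's exact test, p = 0.71). High transcription or open chromatin at these genes was not tested here.

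Replicate 4 shared fewest of its highest regions with the others. The label set alone would not set replicate 4 apart, since replicate 3 carries the same labels. Replicates 3 and 4 shared 28% while replicates 1 and 3, from different label sets, shared 43.5% (26.1% and 43.9% with nuclear regions only). The low share of replicates 3 and 4 is part of the pattern itself, so a label set effect beside another cause stays open. A larger share of background in replicate 4 may account for the pattern: 12% of its highest regions had summits in coding exons, above the 1.35 to 3.87% of the other replicates and towards the 21% of the genome. Read depth, which could have the same effect, was not analysed here.

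Of 45 sets of 4 replicate values examined, 7 held a replicate far from the others; for continuous values chance alone marks about 1 in 20 sets, or 2.25 of these. That rate does not apply to 5 of the 7, all shares of bound genes, where the other replicates had equal counts and any difference marks the set. The promoter share was lowest in replicate 4, 30.7% against 39.5 to 40.4%. The share bound was highest in replicate 2 for hypodermis and seam regulators (10.7% against 0%) and F-box A genes (1.18% against 0.592%), in replicate 4 for neuron identity regulators (2.70% against 0%) and in replicate 3 for pharyngeal genes (5.56% against 0%). For the Notch pathway it was lowest in replicate 1, 0% against 5.88%. TGACTCA was most frequent at summits of replicate 2, 1.35% against 0.595 to 0.695%.

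The mitochondrial genome held 30 regions in replicate 3 and 30 in replicate 4, including the region of highest signal in each, and 0 in replicates 1 and 2. Of these, 29 and 30 were among the highest regions that entered the support counts and the pairs of replicates; location, gene lists and motifs left them out. They also entered the ranks given for replicates 3 and 4, and whether mitochondrial regions were filtered alike in all lists is not given in the sources used here.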

How the results depend on the processing

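No called result changed direction under any alternative run. Direction was not scored for counts or for results that were not called. Some folds of lists not called did cross 1. For cuticle collagens the fold was 0.65 in the main setting and 1.13 with the nearest start alone. For body wall muscle it was 1.12 and, among genes with a merged-list region, 0.501. The promoter share stayed above its background in all 14 alternatives, and the difference between label sets was 5.17 to 7.31 points in all 5. The optimal set holds 518 peaks at the stricter signal limit and 146 with support in all 4 replicates. The number supported by all 4 was 83 and 247 with 518 and 2074 regions per replicate, 92 with summits within 100 bp, 94 with a reciprocal overlap of 50%, and 162 to 309 with a replicate left out, the highest without replicate 4. The 5 called lists became 2 with 500 bp upstream, 8 with the nearest start alone, 3 among genes with a merged-list region, 2 with support in all 4 replicates, and 2 to 4 with a replicate left out. Ribosomal proteins were called in all 14 alternatives and the Hox and TALE list in 13. With support in all 4 replicates, or without replicate 1, 3 or 4, the Hox and TALE call rested on unc-62 and ceh-20 and on no Hox gene. Of these, unc-62 is the locus of the transgene. With the nearest start alone the fold fell to 4.65 from 11.8 for ribosomal proteins and to 10.4 from 16 for Hox and TALE genes. It rose to 10.7 from 8.19 for the heterochronic list and to 10.7 from 5.47 for the pan-neuronal list. The 7 called motifs became 1 with support in all 4 replicates and 1 to 5 with a replicate left out. Leaving out a replicate meant requiring support from the other 3, which left 162 to 309 peaks, so fewer peaks may lower these counts. Each of these sets holds the 146 peaks supported by all 4, so they are not separate tests. Without replicate 1, 2 or 3 some folds fell too, for TGATTGAT to 2, 2 and 3 from 9.25. Those of GAGAGAGA fell to 1.82, 1.91 and 1.71 from 3.54, while those of CACGTG rose to 5, 7 and 8 from 3.75. Random subsets of equal size were not drawn, so set size was not tested. TGACAG was related to signal with 25 bp on each side (rho 0.0714, adjusted p = 0.0423; 0.0423 to 0.184 over its alternatives); the cause was not tested. With the nearest start alone the Wnt pathway (exact test, adjusted p = 0.0129), insulin and longevity (0.00488) and F-box A genes (0.0447, bound less often) gained a call. Circular shifts gave 6 called lists, adding nuclear hormone receptors (permutation test, adjusted p = 0.044). Shifts do not set a list against other genes, and all protein-coding genes together exceeded them (525 bound against a mean of 280.9). The ceh homeobox genes gained a call without replicate 2 (exact test, adjusted p = 0.0219). Of 308 values for single lists, 19 lost and 5 gained their call, and of 99 for single motifs 30 lost it. Chosen after seeing the data were the settings with nuclear regions only (150 peaks supported by all 4; difference between label sets 5.20 points), without peaks at unc-62 (5 lists called), with lists stratified by GC content (4 called), with shuffled bases (7 motifs called) and with each replicate's own regions for location. No paired analysis was possible because there is 1 group. Read depth is unknown, so its limit on any count was not estimated.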

Other observations

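The tests at tRNA, snRNA and snoRNA genes were written before their results were seen; the 6-base words, the longer word, the genes with several summits and the sls-2 genes were examined only after seeing the data.

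Short non-coding RNA genes were frequent at the optimal summits. Within 200 bp of a tRNA gene lay 24 summits against a mean of 3.13 in 1000 circular shifts (fold 7.66, permutation test, adjusted p = 0.00333), and 19 of the 24 were on X, which carries 45.1% of the 612 tRNA genes. The prediction of more summits at snRNA and snoRNA genes was met as well, with 35 summits together. Of these, 10 were at snRNA genes (mean of shifts 0.589) and 25 at snoRNA genes (mean 1.85), both with adjusted p = 0.00333 by permutation. The strongest of these (signal 123.2; I, 4172049 to 4172404) lay at sls-2.4, and 5 of the 18 annotated sls-2 genes, which encode the SL2 spliced leader RNA, had a summit. The replicates held 15 ± 2.83 tRNA, 7.50 ± 1.73 snRNA and 23.5 ± 4.65 snoRNA summits among each one's highest regions (SD, n = 4). Support by at least 2 replicates was found for 11 of the 24 tRNA, 9 of the 10 snRNA and 17 of the 25 snoRNA summits. For all optimal peaks that share was 71.2%. Shifts do not set these genes against other genes, and all protein-coding genes together also exceeded them (525 bound against a mean of 280.9). MicroRNA genes had 5 summits against 1.27 (permutation test, adjusted p = 0.03) and rRNA genes had none.

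In the gene body or 5000 bp upstream, 15 protein-coding genes held at least 4 optimal summits. These counts were not scaled by the length searched, which ran from 6549 bp at mdl-1 to 38613 bp at pqn-41. Per kb, mdl-1 held 0.611 summits, unc-62 0.527, egl-27 0.391, ppfr-1 0.162 and pqn-41 0.104. The highest numbers were 10 at unc-62 and 7 at egl-27 (II, 6835008 to 6847908), which encodes an MTA-type chromatin protein, followed by 5 each at T28B11.1, din-1 and ppfr-1. Genes with 4 were sma-9, zfp-1, mdl-1, let-526, kin-20, ercc-1, pkg-2, pqn-41, W06H8.6 and Y111B2A.12. At Y111B2A.12, 1 of the 4 summits was among the highest regions of at least 2 replicates, the lowest count among these genes. One of the 20 strongest peaks of the whole set (165.4; II, 6823341 to 6823574) was intergenic, 11554 bp upstream of the nearest start, that of egl-27.

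Among all 2080 words of 6 bases, 437 were more and 332 less frequent at summits than in flanks (exact McNemar test with Benjamini-Hochberg adjustment), in windows that also differed in GC content. TGACAG ranked 55 by p. Several of the highest words overlap each other, among them GAGACG (22.3% of summits against 4.44% of flanks), AGACGC (15.5% against 2.22%) and ACGCAG (17.1% against 2.51%). The word CTGCGTCT, chosen from these same overlapping words, lay at 116 summits, 11.2%, against 0.964% of flanks and 1.96% of the rest of the merged list. Its share in the replicates' own highest regions was 7.67% ± 2.90 (SD, n = 4), and 10 of the 116 summits also held TGACAG. No factor was assigned to this word here.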
